A study of Mus musculus with 12 samples.

How the data were processed

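Polyadenylated RNA of mouse ES cells and their differentiated derivatives was sequenced on an Illumina platform in 12 libraries of 3 genotypes, per the labels' protocols. Per the submitters' processing notes reads were aligned with Bowtie2 to the mouse genome mm9, with no version given. The program that counted reads, and whether it used strand or kept reads mapping to several places, is not given in the sources used here. The deposited tables held, for each of 29257 RefSeq transcript models, whole-number read counts, an exon length and an RPKM that the authors made by dividing the counts by exon length and by a library total, larger than the total in genes, as the values themselves show. The models carry 22878 gene symbols, 4019 of them with several models. Models of 1 gene each count the reads they share, so the longest model stood for its gene. Symbols were matched to chromosomes through a RefSeq table used for names and neighbours only (99.7% matched), 336 symbols have models at more than 1 locus, and no coordinates are given.

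Raw counts being present, edgeR 4.0.16 quasi-likelihood tests with TMM scaling were the main test, as laid down before the data were examined, and limma 3.58.1 on the deposited RPKM and DESeq2 1.42.0 (R 4.3.3) were alternatives. Genes with at least 1 RPKM in at least 2 libraries of a fit were tested, and an adjusted p under 0.05 (Benjamini-Hochberg over the genes tested) counted as changed. A standard error is the fold change divided by the square root of the F statistic. The ES comparisons used the 6 ES libraries with 3 residual degrees of freedom, the differentiated comparisons 6 libraries with genotype and day, the comparison of differentiated with ES cells all 12 libraries with genotype, and the interactions and tests within a genotype a mean per genotype and state with day. CPM values are TMM-scaled over the 12 libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the plots. On simulated counts with 400 changed genes the ES test recovered 92.5% of 2-fold and 98.5% of 4-fold changes, the test of differentiated against ES cells 40% and 79.5%, the test of days 7% and 62.5%, the differentiated test of DKO against WT 1.5% and 20%, and the KO interaction 3.5% and 51%.

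The 22 gene lists covered H4K20 methylation enzymes, core and naive pluripotency, primed pluripotency, two-cell-like genes, germline genes, trophoblast, primitive and visceral endoderm, primitive streak and early mesoderm, cardiac muscle, blood and endothelium, neural progenitors and neurons, Hox clusters, feeder fibroblast and mesenchyme, p53 targets, replication licensing and fork, heterochromatin and silencing factors, genome architecture, imprinted genes, canonical Wnt targets, stress and immediate early genes, interferon and double-stranded RNA response, and X inactivation and Y-linked genes. Lists and chromosomes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation camera also has only the few residual degrees of freedom of the fit, so the 2 settings differ in more than the correlation. Chromosome 14 in KO ES cells had an estimated correlation of 0.007, under the preset, yet camera p = 0.0024 against 2.5e-16 with the preset. Failing that test therefore does not show that correlation between genes explains a shift. The named genes were, per comparison, the targeted genes, the 8 largest rises and 8 largest falls among changed genes with at least 5 RPKM in a group and no overlap between groups, and up to 4 members of each list with the smallest adjusted p; other genes named were chosen after their values were seen. Where every library of a group had no reads, the fold was computed against 3 counts per library. Intervals and floors cover counting error only, and no sequence reads, strand or copy number data were analysed here. Alternatives covered the pseudocount, the filter on low values, the scaling, the tool, the libraries in the fit, a replicate block and leaving out each library. A few were added after the data were seen: the transcript model with the most reads, limma on log2(RPKM + 1), and leaving out chromosomes 1, 11, 14, X and Y.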

Results

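Polyadenylated RNA was sequenced from mouse embryonic stem (ES) cells of 3 genotypes. WT cells were compared with cells lacking SUV420H2 (KO) and with cells labelled as lacking both SUV420H1 and SUV420H2 (DKO). These enzymes add the second and the third methyl group to lysine 20 of histone H4, a mark of constitutive heterochromatin. Each genotype had 2 libraries of undifferentiated ES cells, grown without feeders with 1.5 µM of a GSK3 inhibitor, which stabilises beta-catenin, and 1 library each after 8 and 12 days of differentiation, 12 libraries in all. The labels do not say whether the 2 ES libraries of a genotype came from separate cultures, so they may be technical replicates of 1 culture. Their counts differed by more than repeat sequencing of 1 library would give, with a chi-square per degree of freedom of 3.99 in WT, 15.6 in KO and 37.9 in DKO, which does not show separate cultures. Reads counted in genes ranged from 22538336 (KO day 8) to 26675600 (WT day 12) per library. The comparisons ask which transcripts differ without SUV420H2 or without both enzymes, and whether the genotypes change alike during differentiation.

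The targeted genes were examined first. Suv420h2, on chromosome 7, was at 123.1 and 111.9 CPM (reads scaled to library size) in the 2 WT ES libraries. In KO ES cells its mean was 18.2 CPM (SD 1.2), or 15.5% of WT, and in DKO 19.2 CPM (SD 6.0), or 16.4% (n = 2 libraries each). These are log2 fold changes of -2.66 (SE 0.19, edgeR adjusted p = 6.1e-07) and -2.60 (SE 0.19, adjusted p = 2.3e-07). After differentiation Suv420h2 was at 125.8 CPM (day 8) and 121.6 CPM (day 12) in WT, at 26.1 and 39.5 CPM in KO and at 37.3 and 24.7 CPM in DKO. Suv420h1, on chromosome 19, was at 44.7 and 49.8 CPM in WT ES cells, at 40.5 and 43.5 CPM in KO, and at 61.0 and 70.6 CPM in the libraries labelled DKO. Its mean in DKO was therefore 139.2% of WT, a log2 fold change of 0.49 (SE 0.13, edgeR adjusted p = 0.0057), and without WT ES replicate 1 the adjusted p was 0.095. At days 8 and 12 Suv420h1 was at 60.3 and 84.0 CPM in DKO and at 55.2 and 53 CPM in WT. A shorter Suv420h1 transcript model of 3290 bases held 30.2 and 27.7 CPM in WT and 16.6 and 11.6 CPM in DKO ES cells, and at days 8 and 12 17.7 and 19.8 CPM in WT and 15.6 and 17.3 CPM in DKO. A model of 3318 bases held 17.0 and 17.5 CPM in WT and 15.2 and 10.7 CPM in DKO ES cells, and neither model was tested. Counts over whole transcripts cannot show the loss of single exons, so Suv420h1 counts neither show nor exclude a knockout in the libraries labelled DKO. Setd8, the H4K20 monomethyltransferase, was at 149 and 155.2 CPM in WT, 136 and 148.8 CPM in KO and 115.3 and 146.9 CPM in DKO ES cells.

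**Figure D1:**
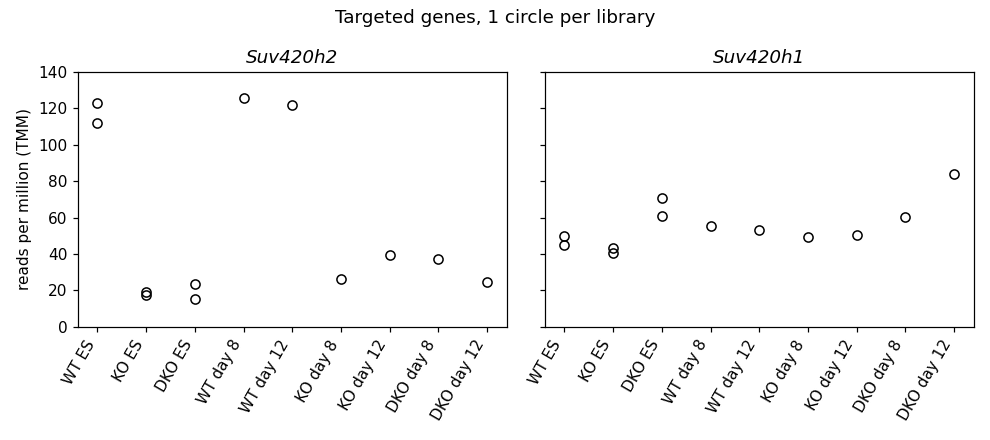
Suv420h2 and Suv420h1 in each library, in CPM. Each circle is 1 library of WT, KO or DKO ES cells or of differentiated cells at day 8 or 12. Suv420h2 lies at 111.9 CPM or more in every WT library and at 39.5 CPM or less in every KO and DKO library, while Suv420h1 lies at 61.0 and 70.6 CPM in the DKO ES libraries.

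KO ES cells differed from WT in genes of early embryos and of germ cells, among others. Pramel7, a preferentially expressed antigen gene of early embryos, went from 0.168 and 0.122 CPM in WT to 68.5 and 57.8 CPM in KO (log2 fold change 8.75, SE 0.29, edgeR adjusted p = 3.2e-09). Olig2, a transcription factor of oligodendrocyte and motor neuron progenitors, rose by 8.41 on the log2 scale (SE 0.26, adjusted p = 1.6e-09), and Obox6, an oocyte homeobox gene, by 6.49 (SE 0.31, adjusted p = 2.9e-08). Nkx6-3, a homeobox gene, fell by 5.27 (SE 0.19, adjusted p = 2.8e-09), and the Y-linked genes Ddx3y and Eif2s3y had no reads in KO, at least 420-fold and 260-fold lower than in WT at a floor of 3 counts per library. Of 12044 genes tested, 5142 changed, 2827 higher and 2315 lower. Of these, 1739 changed at least 2-fold, 1164 higher and 575 lower. The other largest rises were those of Serpina3m (9.81), Pramel6 (9.32), Rpl29 (6.81), Gm8909 (6.72) and Mir692-1, which had no reads in WT and was at least 39-fold higher. The other largest falls were those of Tmem181b-ps (-5.82), Dynlt1b (-4.26), Hist1h2ad (-4.06), Hist1h2ah (-3.93) and Rprl3, which had no reads in KO and was at least 60-fold lower. Pramel, ribosomal protein, histone, Dynlt1, MHC-like and short RNA genes have near-identical copies or lie within other transcripts, so the split of their reads is uncertain. The count was 3399 and 3344 genes without WT ES replicate 1 or 2 and 3206 without KO ES replicate 2.

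Of 22 gene lists fixed before the data were examined, 7 stood apart from other genes in KO ES cells with camera's preset correlation of 0.01, and with an estimated correlation none did. The latter test also has few degrees of freedom, so its failure does not show that correlation explains a list. Of 32 two-cell-like genes, the transcripts of the 2-cell embryo, 11 passed the filter on low values, which genes nearly absent from WT pass only where other libraries hold reads, so the filter favours rises. Of these 11, 10 rose and none fell (10 adjusted over the list alone), among them AU018091 (1.36). Zscan4f, of the Zscan4 cluster, was at 0.0838 and 0 CPM in WT and at 9.53 and 7.07 CPM in KO. The list's median was 6.52, or 5.99 with a gene without reads at its bound, and 1.44 on log2(RPKM + 1) values and 1.40 after their quantile normalization (adjusted p = 6.2e-07; adjusted p = 0.17 with an estimated correlation). Of 19 germline genes 16 rose and 1 fell (17 and 1 adjusted over the list alone), with Smc1b, a meiotic cohesin, at 6.30, Tuba3a, a testis tubulin, at 4.04 and Tex19.1 at 1.81 (adjusted p = 5.8e-08; adjusted p = 0.12 with an estimated correlation). Among 28 p53 targets 19 rose and 1 fell (21 and 1 adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at 1.55, Ccng1 at 1.36 and the death receptor Eda2r at 1.68 (adjusted p = 3.7e-06; adjusted p = 0.12 with an estimated correlation). Among 17 trophoblast genes 12 rose and 1 fell, both adjusted over all genes and adjusted over the list alone, led by Gata3 at 6.12 and Rhox9 at 3.19 (adjusted p = 0.0005; adjusted p = 0.17 with an estimated correlation). Of 32 imprinted genes 19 rose and 7 fell, also when adjusted over the list alone, and H19 (5.11), Peg12 (2.80) and Meg3 (2.05) rose (adjusted p = 0.009; adjusted p = 0.18 with an estimated correlation). Of 39 Hox genes 9 passed the same filter, which favours rises here too. Among these 9, 6 rose and none fell, also when adjusted over the list alone, Hoxb9 by 2.75 and Hoxc13 by 2.49. The list had camera adjusted p = 0.022, and 0.21 with an estimated correlation. Its median was 2.49, but 0.41 on log2(RPKM + 1) values and 0.25 after their quantile normalization. Of 6 X inactivation and Y-linked genes, 4 fell (4 adjusted over the list alone, where 1 also rose), including Uty, without reads in KO and at least 140-fold lower (adjusted p = 0.0011; adjusted p = 0.21 with an estimated correlation).

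Pluripotency genes moved both ways in KO ES cells. Of 34 core and naive genes 13 rose and 11 fell (13 and 12 adjusted over the list alone), and the list did not stand apart (camera adjusted p = 0.64). Zfp42, a naive marker also called Rex1, fell from 2614 and 2476 CPM to 233 and 270.0 CPM (log2 fold change -3.31, SE 0.12, edgeR adjusted p = 2.8e-09), while Nanog rose by 1.46 and the DNA methylation cofactor Dnmt3l by 1.52. Bmp4, a secreted signal of the early embryo, fell by 2.85 on the log2 scale, and the Wnt targets Ccnd2 and Myc fell by 3.10 and 1.67. Among lists that did not stand apart, 8 of 18 primed pluripotency genes rose and 4 fell, as did 11 and 5 of 19 primitive and visceral endoderm genes and 5 and 4 of 11 streak and early mesoderm genes. The same counts were 3 and 1 of 5 cardiac genes, 4 and 2 of 10 blood and endothelial genes, and 10 and 4 of 16 fibroblast and mesenchyme genes. The neural list had 9 of 19 higher and 3 lower, the Wnt list 5 of 16 higher and 7 lower, the stress list 12 of 29 higher and 4 lower, and the interferon list 8 of 15 higher and 4 lower. Against 42.7% of all genes changed, chromatin lists had 3 higher and 4 lower of 33 replication genes, 6 and 5 of 36 heterochromatin factors, 6 and 8 of 31 genome architecture genes and 2 and 1 of 9 H4K20 methylation enzymes and demethylases. Within them the nuclear organiser Satb1 fell by 2.17 on the log2 scale.

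Genes of whole chromosomes shifted together in KO ES cells. X-linked genes were higher, with 338 of 433 higher, 13 lower and a median log2 fold change of 0.91, a 1.88-fold level (camera adjusted p = 4.4e-28). Genes of chromosome 1 were lower, with 384 of 647 lower, 51 higher and a median of -0.57, a 0.67-fold level (adjusted p = 6e-17). Genes of chromosome 14 were also lower, with 259 of 432 lower, 32 higher and a median of -0.53, a 0.69-fold level (adjusted p = 1.7e-15). With an estimated correlation these had adjusted p = 0.075 (X), adjusted p = 0.075 (1) and adjusted p = 0.051 (14). Chromosome 6 had a median of 0.22 (adjusted p = 0.011; adjusted p = 0.2 with an estimated correlation). Fold changes of named genes on these chromosomes, such as Rhox9 and Phf8 on the X chromosome, may hold part of these shifts, but single genes need not follow them.

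**Figure D2:**
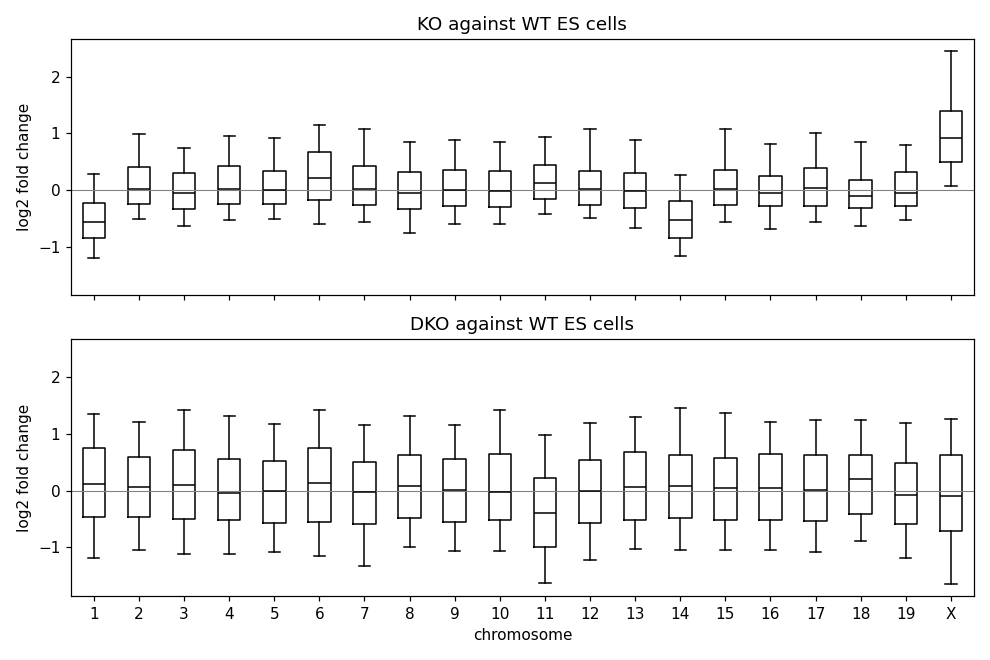
Log2 fold changes of genes per chromosome in KO and DKO against WT ES cells; boxes span the middle quartiles of the genes and whiskers the 10th to 90th percentiles. In KO the medians of chromosomes 1 and 14 lie at -0.57 and -0.53 and that of the X chromosome at 0.91, and in DKO the median of chromosome 11 lies at -0.40.

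In DKO ES cells stress response and primitive and visceral endoderm genes were higher than in WT and Wnt targets and interferon response genes lower by camera's preset correlation, while p53 targets and Hox genes were higher as in KO. None of these lists passed with an estimated correlation. Sox1, a transcription factor of neural progenitors, rose from 22.2 and 22.9 CPM to 487.7 and 438.7 CPM (log2 fold change 4.37, SE 0.13, edgeR adjusted p = 6e-10). Atf3, a stress-induced transcription factor, rose by 4.29 (SE 0.14, adjusted p = 1.5e-09) and Gata4, an endoderm regulator, by 3.71 (SE 0.17, adjusted p = 7.4e-09). Ccnd2, cyclin D2, fell from 216 and 218 CPM to 8.22 and 11.1 CPM (log2 fold change -4.48, SE 0.16, adjusted p = 2.1e-09). Tdrd12, a piRNA pathway gene, fell from 23.0 and 21.4 CPM to 0.0451 and 0 CPM (adjusted p = 2.3e-09). In all, 7692 of 12044 genes changed, 3880 higher and 3812 lower, and 3243 changed at least 2-fold. The other largest rises were those of Olig2 (7.80), Sox6 (7.53), Ripply3 (6.06), Rpl29 (6.04), Pigz (5.38), Klhdc7a (5.22), Wls (5.17) and Mir692-1, at least 150-fold higher than in WT, where it had no reads. The other largest falls were those of Fmr1nb (-6.47), Pla2g1b (-5.92), Calb2 (-5.91) and Mir1906-1 and Mir1906-2, which share their reads and overlap Meg3. Ddx3y and Eif2s3y had no reads in DKO and were at least 410-fold and 250-fold lower.

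In DKO ES cells 6 lists stood apart with the preset correlation and none with an estimated one. Of 29 stress and immediate early genes 20 rose and 6 fell, also when adjusted over the list alone, with Nupr1 at 3.59, Ddit4 at 3.66 and Atf5 at 3.39 (camera adjusted p = 0.00052; adjusted p = 0.48 with an estimated correlation). Of 28 p53 targets 21 rose and 1 fell, also when adjusted over the list alone, with Plk2 at 2.46, Sesn2 at 2.06 and Mdm2 at 1.51 (adjusted p = 2.7e-05; adjusted p = 0.26 with an estimated correlation). Of the 9 Hox genes that passed the filter on low values, which favours rises here as in KO, 8 rose and none fell (9 adjusted over the list alone). Hoxa5 was at 5.80 and Hoxb9 at 5.12. The list had camera adjusted p = 0.00052, and 0.26 with an estimated correlation. Its median was 2.79, but 1.40 on log2(RPKM + 1) values and 1.37 after their quantile normalization. Of 19 primitive and visceral endoderm genes 12 rose and 4 fell, also when adjusted over the list alone, Apoe by 2.12 and Sox7 by 2.24 (adjusted p = 0.022; adjusted p = 0.32 with an estimated correlation). Among 16 Wnt targets 2 rose and 10 fell (2 and 12 adjusted over the list alone), with Notum at -4.37, Myc at -3.23 and Ccnd1 at -1.51 (adjusted p = 0.0036; adjusted p = 0.26 with an estimated correlation). Among 15 interferon and double-stranded RNA response genes 2 rose and 11 fell, also when adjusted over the list alone, Oas1a by -5.43 and Ifitm1 by -3.84 (adjusted p = 0.01; adjusted p = 0.53 with an estimated correlation).

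Pluripotency and imprinted genes also changed in DKO without standing apart as lists. Of 34 core and naive pluripotency genes 9 rose and 15 fell, with Tbx3 at 2.66 and Zfp42 at -3.05, and of 18 primed genes 4 rose and 9 fell, with Otx2 at 2.35, Dnmt3b at -2.43 and Zic2 at -3.54. Meg3 and Rian, non-coding RNAs of the imprinted Dlk1-Dio3 region, fell by 5.10 and 7.10 on the log2 scale, and of 32 imprinted genes 12 rose and 14 fell. Of 19 germline genes 3 rose and 9 fell, Tex19.1 by -2.22, and of 11 two-cell-like genes none rose and 5 fell (3 adjusted over the list alone), AU018091 by -2.33 and Eif1a by -0.74. Several of these 11 lay near the floor in WT too: 5 had no reads in WT or in DKO, and 3 gave no fold at the floor of 3 counts. Pramel7 was lower by at least 1.1-fold at that floor. The list's median was -0.74, or -0.23 with genes without reads at their bounds. Genes of chromosome 11 were lower, with 532 of 1040 lower, 210 higher and a median of -0.40, a 0.76-fold level (camera adjusted p = 0.00049; adjusted p = 0.36 with an estimated correlation). Chromosomes 1, 14 and X had medians of 0.12, 0.08 and -0.09 in DKO.

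Set directly against KO, DKO ES cells held fewer early embryonic and germ cell transcripts. Pramel6, Pramel7 and Zscan4f had no reads in DKO and were at least 500-fold, 470-fold and 61-fold lower than in KO. Of 11 two-cell-like genes, of which those nearly absent from DKO passed the filter through other libraries, 10 fell and none rose. Their median was -6.61, or -5.94 with genes without reads at their bounds, and -1.56 on log2(RPKM + 1) values and -1.48 after their quantile normalization (camera adjusted p = 3.3e-05; adjusted p = 0.34 with an estimated correlation). Of 19 germline genes 16 fell and 2 rose, Tuba3a by -7.85 and Tex19.1 by -4.03 (adjusted p = 4.1e-05; adjusted p = 0.34 with an estimated correlation). Stress genes were higher, 20 of 29 with 5 lower, with Atf3 at 3.77 (adjusted p = 0.0013; adjusted p = 0.37 with an estimated correlation). Wnt targets were lower, 12 of 16 with 2 higher, with Notum at -5.20 and Lef1 at -5.63 (adjusted p = 0.012; adjusted p = 0.34 with an estimated correlation). These 4 list counts were the same when adjusted over the list alone. Nanog (-2.52), Zic2 (-4.31) and Rian (-9.11) fell, while Ripply3 rose by 7.71, Nkx6-3 by 7.14 and Bmp4 by 3.08. Of 12044 genes 8110 changed, 4006 higher and 4104 lower in DKO, 3697 of them at least 2-fold. Suv420h2 did not pass the test (0.05, SE 0.19, adjusted p = 0.81).

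The changes of KO and DKO against WT overlapped in part. Olig2, Rpl29, Plagl1 and Cdkn1a were higher in both and Zfp42, Ccnd2, Myc and Suv420h2 lower in both, while Meg3, Tex19.1, Oas1a and Dnmt3b were higher in KO and lower in DKO. In the same direction 1258 genes were higher and 908 lower, 2166 in all, against 911 and 733 for independent lists of these sizes, and 1289 genes changed in opposite directions. In each of 20 simulations of unchanged groups against the shared WT libraries the overlap was 0. These leave out any effect, so few genes can pass in them and that 0 is no baseline for lists of this size. At least 2-fold, 402 genes were higher and 164 lower in both, against 161 and 75 for independent lists, and 289 moved apart. The correlation of fold changes across genes, which are not independent, was 0.18 (mean of 0.49 in the simulations) and their covariance was 0.21 (0.025 in the simulations). Both comparisons use the same 2 WT libraries, so part of the excess may come from them.

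In a fit over the 3 genotypes pluripotency genes were lower and genes of endoderm, mesoderm, blood and mesenchyme higher after differentiation by camera's preset correlation, though not each within DKO. None of these lists passed with an estimated correlation. Ihh, a hedgehog signal of visceral endoderm, rose by 5.77 on the log2 scale (SE 0.50, edgeR adjusted p = 0.00046), Foxa2, an endoderm regulator, by 5.44 (SE 0.48, adjusted p = 0.00046) and Flt1, a VEGF receptor, by 5.46 (SE 0.53, adjusted p = 0.00056). Tfcp2l1, a naive pluripotency factor, fell by 2.87 (SE 0.29, adjusted p = 0.00059). The fit of all 12 libraries had terms for ES cells, for each day and for genotype, so the genotypes served as replicates of a day. It called 4883 of 13429 genes changed, 2629 higher and 2254 lower. Apoa4, an apolipoprotein without reads in any ES library, was at 23.9 and 111 CPM in WT at days 8 and 12. Other genes with large changes were Plek (9.84), Prss12 (8.27), Clic6 (7.56), Tmem176b (7.48) and Prdm6 (7.43), and Jam2 (-4.09), Irak3 (-3.68), Tlx3 (-3.21) and Mylpf (-3.11). The share of higher calls was 53.8%, against 66.9% to 67.2% with limma on RPKM, where the median of all genes lay at 0.09 to 0.12, and 43.4% after quantile normalization. The count was 3035 without WT ES replicate 1 and 3018 without WT ES replicate 2.

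Most lists moved with differentiation by camera's preset correlation, 16 of 22, and none with an estimated one. Of 37 primitive and visceral endoderm genes 28 rose and none fell (30 adjusted over the list alone; median 4.15, or 2.46 on log2(RPKM + 1) values and 2.24 after their quantile normalization), among them Dab2 at 6.33 (adjusted p = 1.9e-11; adjusted p = 0.4 with an estimated correlation). Of 35 mesenchymal genes 25 rose (27 adjusted over the list alone), with the smooth muscle actin Acta2 at 9.66 and Mmp2 at 3.23 (adjusted p = 1.7e-08; adjusted p = 0.42 with an estimated correlation). Of 34 blood and endothelial genes 22 rose (27 adjusted over the list alone), with Runx1 at 4.16 (adjusted p = 1.7e-08; adjusted p = 0.42 with an estimated correlation). Of 26 streak and early mesoderm genes 16 rose and 2 fell, Lhx1 by 6.27 (adjusted p = 0.00019; adjusted p = 0.4 with an estimated correlation). Of 22 cardiac genes 9 rose, Actc1 by 7.20 (adjusted p = 0.0012; adjusted p = 0.42 with an estimated correlation). Of 31 Hox genes 11 rose, Hoxb3 by 5.06 (adjusted p = 0.00024; adjusted p = 0.47 with an estimated correlation). Of 34 core and naive pluripotency genes 22 fell and none rose (28 adjusted over the list alone), Spp1 by -3.07 (adjusted p = 6.8e-10; adjusted p = 0.4 with an estimated correlation). Of 33 replication genes 25 fell and none rose (27 adjusted over the list alone), Mcm5 by -1.13 (adjusted p = 5.4e-10; adjusted p = 0.4 with an estimated correlation). Of 20 neural genes 7 fell and 1 rose, Sox1 by -2.50 (adjusted p = 0.014; adjusted p = 0.4 with an estimated correlation).

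The extent of differentiation differed by genotype. In the test within each genotype 8199 genes changed in WT, 3933 in KO and 2641 in DKO. The days serve as replicates there, and their spread is pooled with that of the ES pairs. Pou5f1, the gene of the core pluripotency factor OCT4, went from 1785 and 1788 CPM in WT ES cells to 114 and 56.1 CPM at days 8 and 12, while it was at 1050.0 and 409 CPM in KO and at 1788 and 943.5 CPM in DKO at these days. Within WT 32 of 34 core and naive pluripotency genes fell (camera adjusted p = 5.3e-14; adjusted p = 0.0058 with an estimated correlation). Within KO 28 fell (adjusted p = 1e-12; adjusted p = 0.0073 with an estimated correlation). Within DKO 10 fell and 2 rose (adjusted p = 0.011; adjusted p = 0.15 with an estimated correlation). Among lists that did not stand apart within DKO, blood and endothelial genes had 2 of 34 higher and 1 lower (median 0.20, camera adjusted p = 0.18). Mesenchymal genes had 3 of 35 higher (median 0.75, adjusted p = 0.33) and cardiac genes 0 of 22 changed (median 0.33, adjusted p = 0.89). Not all lists lagged alike: DKO primitive and visceral endoderm genes had a median log2 ratio to WT of -2.49 at day 8 and -0.72 at day 12, in single libraries without a test. On the first principal component, which held 53.4% of the variance, WT lay at 144.1 and 144.7 at days 8 and 12, KO at 19.2 and 103.2, DKO at -37.5 and 30, and the 6 ES libraries between -79.1 and -53.

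Between day 8 and day 12, with the 3 genotypes as replicates, no gene passed edgeR's test, with 1080 genes at an unadjusted p under 0.05, 101 genes by DESeq2 and 0 by limma. Afp, the fetal albumin of visceral endoderm, was at 15.2 and 80.3 CPM at the 2 days in WT, at 1.21 and 92.2 CPM in KO and at 0.652 and 51.3 CPM in DKO. Primitive and visceral endoderm genes had a median log2 difference of 1.86 (camera adjusted p = 1.3e-20; adjusted p = 0.39 with an estimated correlation), with 11 of 37 higher adjusted over the list alone, Lamc1 at 1.62 (SE 0.60). Replication genes had a median of -0.52 (adjusted p = 1.6e-10; adjusted p = 0.43 with an estimated correlation) and pluripotency genes one of -0.89 (adjusted p = 0.00012; adjusted p = 0.7 with an estimated correlation). Without WT day 8, WT day 12 or KO day 8, 11, 2 and 1 genes passed.

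Some pluripotency genes were higher in differentiated DKO cells than in WT and Col1a1, Meg3 and Rian lower, while no list stood apart with an estimated correlation. Each genotype has 1 library per day, so the days serve as its replicates and the test asks for differences shared by both. In DKO 281 of 12896 genes passed, 196 higher and 85 lower. Lefty2, a Nodal antagonist, rose by 5.81 (SE 0.25, edgeR adjusted p = 0.036), Tdgf1, a Nodal coreceptor, by 4.33 (SE 0.23, adjusted p = 0.036) and Pou5f1 by 4.02 (SE 0.26, adjusted p = 0.036). Col1a1, the chain of type I collagen, was at 1333 and 930.5 CPM in WT and at 0.826 and 1.26 CPM in DKO at days 8 and 12 (log2 fold change -10.29, SE 1.22, adjusted p = 0.047). Other large changes in DKO were those of Olig1 (8.38), Olig2 (7.91), Rpl29 (6.94), Pou4f2 (6.55), Lefty1 (5.99) and Sox1 (5.86), and of Meg3 (-9.93), Zim1 (-9.37), Rian (-8.56) and Col6a1 (-7.62). The share of higher calls was 69.8% by edgeR, 41.7% by DESeq2 and 47.9% to 49% with limma on RPKM. The count was 187 without WT day 8 and 1816 without WT day 12, and 0 without any 1 of KO day 8, KO day 12, DKO day 8 and DKO day 12. The calls of single genes are lost there, while the fold change of Pou5f1 was 3.95 and 3.94 without KO day 8 or day 12 and 4.16 and 3.83 without DKO day 8 or day 12.

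In differentiated DKO cells 18 of 34 core and naive pluripotency genes rose and none fell (31 adjusted over the list alone; camera adjusted p = 2.4e-16; adjusted p = 0.22 with an estimated correlation). Of 35 mesenchymal genes 4 fell (27 adjusted over the list alone; median -4.88, or -2.87 on log2(RPKM + 1) values and -2.70 after their quantile normalization; adjusted p = 5.2e-14; adjusted p = 0.34 with an estimated correlation). Blood and endothelial genes had a median of -4.61, or -2.67 and -2.49 on these scales, with 23 of 34 lower adjusted over the list alone (camera adjusted p = 2.1e-10, and 0.36 with an estimated correlation). The embryonic globin genes Hba-x and Hbb-bh1 had no reads in DKO and were at least 7900-fold and 5200-fold lower, though neither passed over all genes. Of 40 imprinted genes 5 fell, 26 adjusted over the list alone (median -2.68, or -1.91 and -1.67 on these scales; adjusted p = 2.9e-09; adjusted p = 0.34 with an estimated correlation). H19 fell by 7.32 on the log2 scale. In KO no gene of 12896 passed edgeR's test, with 3002 at an unadjusted p under 0.05, 1836 by DESeq2, 136 by limma and a smallest adjusted p of 0.0613. KO pluripotency genes had a median of 2.45 (24 higher and 1 lower adjusted over the list alone; adjusted p = 2.3e-13; adjusted p = 0.15 with an estimated correlation), with Pou5f1 at 3.04 (SE 0.25, edgeR adjusted p = 0.075) and Lefty2 at 4.21 (SE 0.23, adjusted p = 0.061). KO primitive and visceral endoderm genes had a median of -2.51 (24 lower adjusted over the list alone; adjusted p = 1.7e-13; adjusted p = 0.38 with an estimated correlation).

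At single days, where no test was made, lists were set against 10000 random lists matched on expression. The pluripotency list had a median log2 ratio to WT of 2.52 in KO at day 8 and 2.65 at day 12, and of 2.91 and 3.05 in DKO at these days, each above every random list at the 100th percentile. Blood and endothelial genes in KO went from -3.48 at day 8 (percentile 0) to 1.40 at day 12 (percentile 100), and in DKO from -5.72 to -2.82 (both at percentile 0). Cardiac genes in KO had a median of -2.28 at day 8 (percentile 0.1) and 0.90 at day 12 (percentile 95.8), and in DKO -4.23 and -3.02 (both at percentile 0). Mesenchymal genes were at -3.75 in KO at day 8 and -0.62 at day 12, and at -5.81 and -4.37 in DKO (all at percentile 0).

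**Figure D3:**
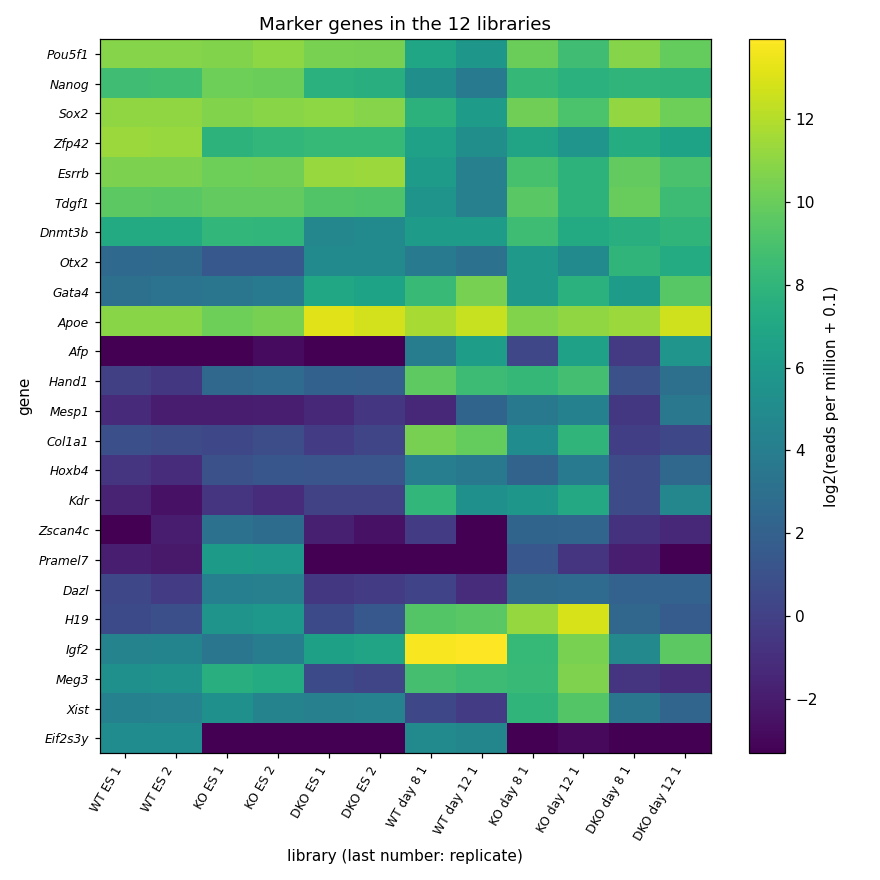
Levels of marker genes in the 12 libraries, as log2 of CPM plus 0.1, for genes chosen after their values were seen; rows are genes and columns are the WT, KO and DKO libraries of ES cells and of days 8 and 12. Pou5f1 is at 1788 CPM in DKO at day 8 and at 114 CPM in WT at day 8.

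The genotype effects themselves differed between differentiated and ES cells. The KO effect on Tdgf1 was higher by 3.49 after differentiation (log2 scale, SE 0.18, edgeR adjusted p = 0.00032), on Lefty2 by 3.40 (SE 0.18, adjusted p = 0.00032) and on Pou5f1 by 2.97 (SE 0.23, adjusted p = 0.00079). The DKO effect on these genes was higher by 4.61, 6.70 and 4.34 (adjusted p = 2.3e-05, 4.1e-06 and 4.9e-05). Xist, the RNA that coats the inactive X chromosome, was at 40.0 and 21.2 CPM in KO ES cells and at 254.1 and 631.2 CPM in KO at days 8 and 12. In WT Xist fell from 18.8 and 20 CPM in ES cells to 1.21 and 0.739 CPM at these days. Its interaction, to which the rise in KO and the fall in WT both add, was 8.14 (SE 0.85, edgeR adjusted p = 0.0021). That of its antisense partner Tsix, whose reads cannot be told from those of Xist without strand, was 6.93. Over all genes 2190 of 13429 differed for KO, 1218 higher and 972 lower, and 5638 for DKO, 2839 higher and 2799 lower. The days serve as replicates of a differentiated genotype, and 1 estimate of the spread is shared with the ES pairs. These p-values therefore rest in part on the spread between ES libraries that may share 1 culture. For KO, Spock1 (-8.55), Gata3 (-8.01) and Cited1 (-7.15) were lower and Trh (4.36) higher. For DKO, Fgf17 (8.34), Trh (8.28) and Lefty1 (7.58) were higher and Twist2 (-10.65), Hoxa5 (-6.61) and Hand1 (-9.52) lower. The KO count was 421 and 395 without WT ES replicate 1 or 2, 598 and 534 without KO ES replicate 1 or 2 and 3891 without WT day 12. The DKO count was 3612 and 3616 without WT ES replicate 1 or 2.

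Among lists, the interaction for the 34 core and naive pluripotency genes had 24 higher and 1 lower for KO (27 and 1 adjusted over the list alone; camera adjusted p = 4e-13; adjusted p = 0.0068 with an estimated correlation). It had 28 higher and 1 lower for DKO (29 and 1 adjusted over the list alone; adjusted p = 2.4e-12; adjusted p = 0.0078 with an estimated correlation). Of 33 replication genes 17 were higher for KO (26 adjusted over the list alone; adjusted p = 6e-10; adjusted p = 0.0075 with an estimated correlation). For DKO 25 were higher (26 adjusted over the list alone; adjusted p = 7.7e-07; adjusted p = 0.02 with an estimated correlation), with Mcm10 at 1.61. Of 21 germline genes 14 were higher and 1 lower for DKO (16 and 1 adjusted over the list alone; adjusted p = 2.7e-05; adjusted p = 0.033 with an estimated correlation), with Rpl10l at 5.21 and Hsf2bp at 3.37. Of 31 Hox genes 25 were lower for DKO (27 adjusted over the list alone; adjusted p = 2.2e-11; adjusted p = 0.1 with an estimated correlation). For KO 11 were lower (16 lower and 1 higher adjusted over the list alone; adjusted p = 2.2e-09; adjusted p = 0.13 with an estimated correlation). Of 35 mesenchymal genes 28 were lower for DKO (28 adjusted over the list alone; adjusted p = 1.5e-09; adjusted p = 0.35 with an estimated correlation). For KO 7 were lower (7 adjusted over the list alone; adjusted p = 9.5e-06; adjusted p = 0.4 with an estimated correlation). Of 37 endoderm genes 18 were lower for KO and 17 for DKO (23 and 18 adjusted over the list alone), with Sparc at -3.08 and -2.82 (adjusted p = 7e-12 and 3.7e-05; adjusted p = 0.13 and 0.38 with an estimated correlation).

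**Figure D4:**
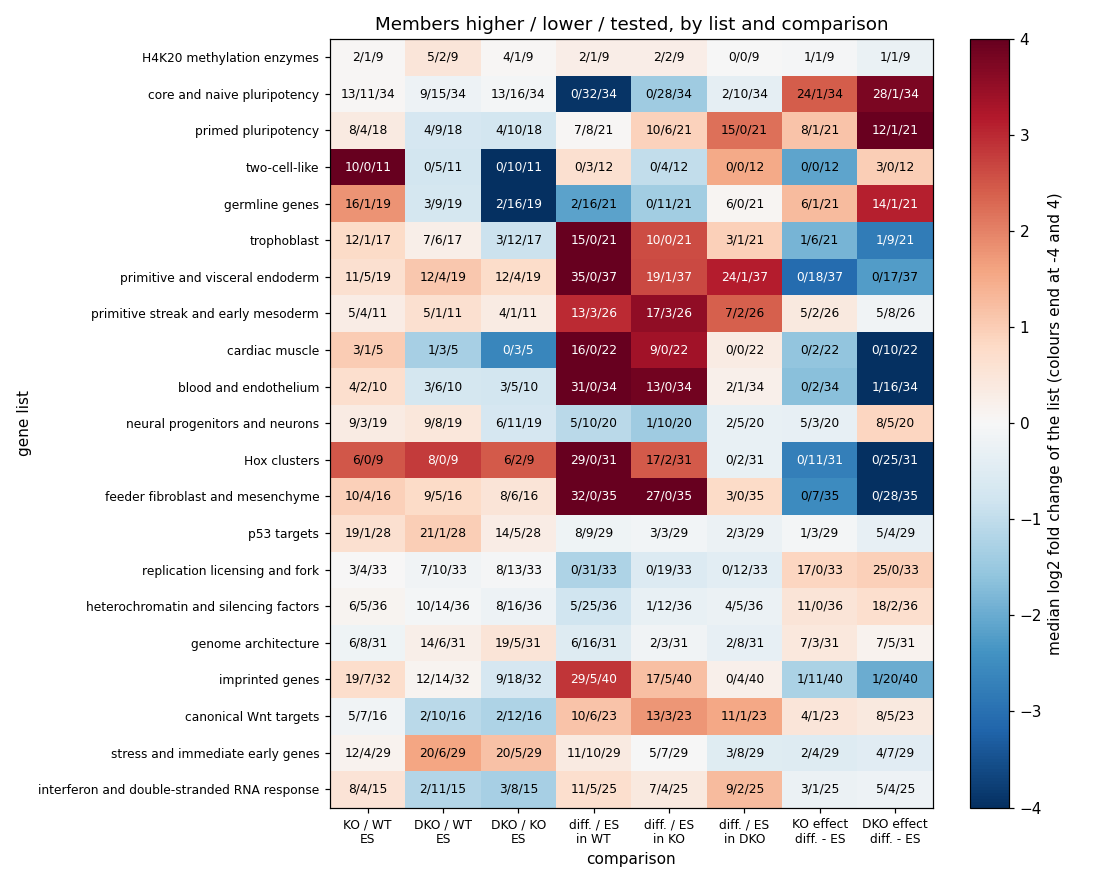
Median log2 difference of each gene list except X inactivation and Y-linked genes, with the number of members higher, lower and tested written in each cell. Columns are the ES comparisons, differentiated against ES cells within each genotype, and the KO and DKO interactions. Colours are capped, so the largest medians cannot be read from them. Core and naive pluripotency genes have medians of 2.42 and 3.77 in the KO and DKO interactions, and two-cell-like genes one of 6.52 in KO against WT ES cells.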

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

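The tests of sample labels, of the scale and of a slower course of differentiation were chosen after the results were seen; the other tests of this part were laid down before.

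The effect of genotype differed between differentiated and ES cells in the test of that difference itself. It did so for 2190 genes in KO and 5638 genes in DKO. The 2 days stand in as replicates of a differentiated genotype there, and their spread is pooled with that of the ES pairs. Those pairs may share 1 culture, so the counts may be too high. KO against WT in differentiated cells gave 0 genes in its own fit and 3698 with all 12 libraries. As lists, core and naive pluripotency genes had median log2 differences of 2.42 for KO and 3.77 for DKO, replication licensing and fork genes 0.86 for KO and 0.96 for DKO, and germline genes 3.12 for DKO, which was 0.83 on log2(RPKM + 1) values and 1.06 after their quantile normalization.

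Behind these values, KO and DKO differentiated libraries lie between ES cells and WT differentiated libraries. Exchanged genotype labels argue little for this. Suv420h2 and Y-linked reads, which tell only WT from the others, matched the label in 6 of 6 differentiated libraries. Genes of chromosomes 1 and 14, lower in KO, matched it in 4 of 4 of KO (-0.48 and -0.43) and DKO (0.08 and 0.11). DKO day 8 correlated across genes with a DKO ES library at 0.931 at most (0.930 with a WT ES library, whose Y-linked reads it lacks), against 0.987 between the DKO ES replicates. Those replicates may share 1 culture, so this cannot tell whether ES cells of another DKO culture lie under the day 8 label. In DKO day 8, genes that fell in WT kept a median of 104.5% of their DKO ES level. Unchanged ES cells mixed into WT-like differentiated cells would leave about 1 shared fraction of the ES level for genes that fall in WT. The 90th percentile of that fraction was at least 5.2 times the 10th, against 1.63 (KO) and 1.93 (DKO) for the ratio between ES replicates. A mixture stays open, since WT-like cells add their own remaining level and undifferentiated cells may themselves change by days 8 and 12. The scale is argued against for both lines: quantile normalization left the pluripotency median at 1.69 for KO and 2.91 for DKO, against 1.65 and 2.77 on the same log2(RPKM + 1) values before it, and DESeq2 size factors gave 2.37 and 3.73. Slower differentiation along the WT course may account for KO, whose changes had slopes of 0.34 (day 8) and 0.69 (day 12) on the WT change with correlations across genes of 0.65 and 0.85, and for DKO it stays open, with slopes of 0.02 and 0.31 and correlations of 0.03 and 0.5, since only the 1 library of day 8 departs from it. The lines also differ beyond the targeted genes: Y-linked genes had 2551 and 2643 reads in the WT ES libraries and 0 in each KO and DKO ES library. Whether such differences account for the pattern stays open and was not tested. Each genotype may rest on 1 line, so effects of genotype and of line cannot be told apart here.

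Of 100 regroupings of libraries within genotypes, 1, the real one, gave as many genes changed between differentiated and ES cells: 4883, against 3554 in the highest other, which exchanged DKO day 8 with a DKO ES library, so chance can be excluded if the libraries are independent, which 2 ES libraries of 1 culture would not be. For day 12 against day 8 the 10 splits of 6 libraries are too few for a share under 0.05: the real split gave 0 genes, all 10 gave as many or more, and the highest other gave 2632, setting WT day 8, WT day 12 and KO day 12 against the rest. So many calls point to a structure of the samples other than the day.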

How the results depend on the processing

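The alternatives with the transcript model with the most reads, limma on log2(RPKM + 1) and leaving out chromosomes 1, 11, 14, X and Y were chosen after the data were seen. Over all alternatives 154 counts of changed genes stayed within 1.5 times and 46 moved, and single genes gave the same call 14502 times, lost it 616 times, gained it 98 times and reversed or came to about 0 in 6 cases. Single lists kept their call 170 times and lost it 139 times, 98 of these with an estimated correlation. Where a count or a call moved, the cause was not tested, except that the 2-fold limit and the stricter filter pass fewer genes by construction.

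For KO against WT in ES cells the count was 3265 with at least 5 RPKM, 1739 at least 2-fold, 2022 with all 12 libraries in the fit, and 3206 to 6368 without 1 library. For DKO against WT it was 3243 at least 2-fold and 5089 with all 12 libraries, for DKO against KO 3697 at least 2-fold, and for their overlap 566 at least 2-fold. Differentiated against ES cells gave 2475 at least 2-fold, 8199 within WT, 2641 within DKO, and 3018 to 5442 without 1 library. Day 12 against day 8 gave 2 with quantile normalization, 101 with DESeq2 and 0 to 11 without 1 library. KO against WT in differentiated cells gave 160, 155 and 136 with limma on log2(RPKM + 0.1), log2(RPKM + 0.5) and log2(RPKM + 1), 7 with no filter, 52 with quantile normalization, 1836 with DESeq2 and 3698 with all 12 libraries. DKO against WT gave 911, 821 and 714 with the same limma settings, 498 with quantile normalization, 3139 with DESeq2, 5089 with all 12 libraries and 0 to 1816 without 1 library. The KO interaction gave 3308 with DESeq2 and 395 to 3891 without 1 library, and the DKO interaction 3612 to 6764 without 1 library. Between differentiated and ES cells Xist within KO (3.88) and, within DKO, Pramel7 (3.65) and Hbb-y (-3.27) took the opposite sign, while Phf2 (-0.01), Pramel6 (0) and Hoxc8 (-0.06) lay about 0 within DKO.

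With an estimated correlation, 0 lists passed in the 3 ES comparisons, in differentiated against ES cells, between days and in both differentiated comparisons, and 2 and 3 in the KO and DKO interactions. That setting also lowers the degrees of freedom to those of the fit, so the loss of lists cannot be put down to correlation alone. With fry 15, 22 and 21 lists passed for KO against WT, DKO against WT and DKO against KO in ES cells, 0 between days, and 6 and 9 for KO and DKO against WT in differentiated cells. Chromosomes shifted in DKO against WT ES cells numbered 1 to 2 without 1 library, and 0 in the 3 ES comparisons with an estimated correlation. Replicate numbers did not pair the libraries, with correlations of deviations of -0.038, -0.037 and -0.042, and with a replicate block 4790, 7437 and 7864 genes changed for KO against WT, DKO against WT and DKO against KO, and 1983 the same way in both KO and DKO. Leaving out a library can leave a group with 1, which is then assumed to vary like the others. In the ES comparisons the filter on low values left 5 of 32 cardiac, 9 of 39 Hox and 11 of 32 two-cell-like genes to test, so most members of these lists have no result there.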

Other observations

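The tests of loss of SUV420H2 alone and of MAPK feedback genes were chosen after the results were seen; those of chromosome number and of paralogs were laid down before.

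Values of 3 imprinted genes, chosen after their values were seen, are given for the differentiated libraries. Igf2, the fetal growth factor, was at 14010 and 15750 CPM in WT at days 8 and 12, at 302 and 1407 CPM in KO and at 27.7 and 780.8 CPM in DKO. H19, its neighbouring non-coding RNA, was at 628 and 749.8 CPM in WT, at 2365 and 7710 CPM in KO and at 5.09 and 3.18 CPM in DKO. Meg3 was at 467 and 364 CPM in WT, at 336 and 1574 CPM in KO and at 0.522 and 0.353 CPM in DKO. The KO and DKO values at each day come from single libraries and have no replicate check.

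In DKO ES cells, where 63.9% of all genes tested changed against WT, members of further lists moved in both directions. Of 31 genome architecture genes 14 were higher, Sun2 by 1.60 and the cohesin loader Mau2 by 1.09, and 6 lower, Lmnb2 by -0.73. Of 36 heterochromatin and silencing factors 10 were higher and 14 lower, among them Setdb1 (-0.76), the H3K9 methyltransferase of silenced repeats, and Jarid2 (-0.82), while of 33 replication genes 7 were higher and 10 lower, Gmnn by -1.19. Neural genes had 9 of 19 higher and 8 lower, trophoblast genes 7 of 17 higher and 6 lower, and blood and endothelial genes 3 of 10 higher and 6 lower. Mesenchymal genes had 9 of 16 higher and 5 lower, streak and early mesoderm genes 5 of 11 higher and 1 lower, and cardiac genes 1 of 5 higher and 3 lower.

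Genes of chromosomes 1, 14, X and Y in KO, and of 11 and Y in DKO, shifted as a whole against WT ES cells by camera's preset correlation, as did chromosome 6 in KO (median 0.22), which was not followed further, but none with an estimated one (adjusted p = 0.051 to 0.2 in KO and 0.36 in DKO). The Y-linked genes Ddx3y, Eif2s3y and Uty together had 0 reads in each KO and DKO ES library, against 2551 and 2643 in the WT ES libraries. They had at most 2 in a differentiated KO or DKO library. Each comparison with WT thus sets a line with almost no Y-linked transcripts against one that has them. For the other chromosomes a difference in chromosome number between the lines may account for the shifts and stays open: of 10 stretches along each chromosome, 10 of 10 lay on the side of the shift for chromosomes 1 (medians of -0.66 to -0.36), 14 (-0.81 to -0.44) and X (0.60 to 1.25) in KO and 11 (-0.53 to -0.28) in DKO. Yet 10 of 10 also lay on 1 side for chromosome 11 in KO (0.03 to 0.30) and chromosome 1 in DKO (0 to 0.32), which did not pass as wholes (adjusted p = 0.085 and 0.94), so the side alone does not decide. On the X chromosome 110 genes listed at a single locus with at least 10 RPKM in WT ES cells kept a median of 0.70, against 0.91 for all its genes. Symbols with several loci thus do not account for most of that shift. Paralogs under other symbols were not left out, so reads shared with them stay open. Loss of SUV420H2 alone was tested through DKO, which had medians of 0.12, 0.08 and -0.09 on chromosomes 1, 14 and X. This argues against an effect of SUV420H2 loss that arises with or without SUV420H1. DKO is labelled as lacking SUV420H1 too and may be another line, so an effect that needs SUV420H1 stays open. A ratio of lines does not show which line departs from the usual number, and copy number was not analysed here.

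Two-cell-like and germline genes were higher in KO and not in DKO ES cells by camera's preset correlation (adjusted p = 0.17 and 0.12 in KO with an estimated one). Loss of SUV420H2 alone argues poorly for this, since both lines lack it and the list medians in DKO against WT were -0.74 and -0.71, against -0.04 and -0.26 on log2(RPKM + 1) values and 0.02 and -0.19 after their quantile normalization, and the first was -0.23 with genes without reads at their bounds. Reads shared between paralogs may add to it: members without a sibling gene were too few to decide, 2 of 2 germline genes higher (Dazl and Mael) and 0 of 0 two-cell-like genes. Presence of SUV420H1 without SUV420H2, or a difference between lines, stays open and was not tested.

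Some genes known to respond to the number of active X chromosomes moved in KO ES cells. Klhl13 rose by 5.42 and Dusp9 by 1.64, both X-linked, and the MAPK feedback genes Spry4 and Dusp6 fell by 2.20 and 1.81 on the log2 scale. In DKO Klhl13 fell by 0.89 and Dusp6 rose by 1.30, while Dusp9 rose by 1.25 and Spry4 fell by 0.74 as in KO. A hypothesis is that 2 active X chromosomes lowering MAPK signalling could contribute in KO. The 11 other MAPK feedback genes had medians of -0.19 in KO (5 lower, 1 higher) and -0.69 in DKO (6 lower, 4 higher), which does not decide it. Xist at 254.1 and 631.2 CPM in KO at days 8 and 12, against 10.8 and 4.83 CPM in DKO, was not predicted in advance.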
